A study of Pseudomonas protegens with 6 samples.

How the data were processed

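RNA sequencing was used to compare *Pseudomonas protegens* H78, a plant-associated pseudomonad that makes antibiotics, with its (p)ppGpp0 mutant, which lacks relA and spoT. RelA and SpoT make the alarmone (p)ppGpp, and SpoT also degrades it. Per the labels, both strains were grown in KMB medium at 28 °C to late exponential phase, at an OD600 between 5.0 and 6.0. Total RNA was purified with column kits and DNase, and rRNA was removed before cDNA libraries were made. There were 3 samples of each strain. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

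The submitters' processing notes name Trimmomatic, TopHat2 2.0.9 and HTSeq 0.6.1 without giving their roles. The genome build is not given in the sources used here, and coordinates are those of the deposited table. The authors deposited 1 table with expected counts per gene and sample, which are not normalized. It has 6446 genes with locus tags, of which 6290 are coding, 75 are tRNA, 64 are other non-coding RNAs, 16 are rRNA and 1 is the transfer-messenger RNA. A symbol was given for 2175 genes, and 143 had no count in any sample. Between 21 and 24 values per sample were not whole within a tolerance of 1e-06, mostly in genes with near-identical copies. The deposited table also has FPKM values (scaled for gene length and depth) for each sample, the authors' mean normalized signal per strain, the ratio of those means as a fold change, its log2 value, and the authors' p-value and adjusted p-value. Of these columns, the fold change and adjusted p were used only to count the authors' calls, and the FPKM values were not used here. Per the file headers, the column names of the comparison are those DESeq writes, and no source used here states the version.

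Columns were matched to samples by strain and replicate number in their names. The mutant columns carry an abbreviation with the replicate number, and as a check the deposited mutant mean was rebuilt from them alone. The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10), which left 5888 genes. Library sizes were scaled with TMM factors, and mutant and wild type were compared with the quasi-likelihood F test without a replicate block. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called higher or lower. CPM values are TMM-normalised counts scaled to a library of 1e6, given as mean ± SD over 3 replicates. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. For genes with no count in 1 strain, the fold is a lower bound computed at 3 counts over the group. With 1 to 3 counts in a strain, the ratio is given with an exact 95% Poisson interval. Such bounds and intervals cover counting error only. A value of 3 counts in 1 library corresponded to between 0.542 and 0.644 CPM.

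Before the data were examined, 31 gene lists were fixed from symbols and product names. A gene belonged to a list if its symbol matched, or, without a symbol, if its product description matched. Ignoring copy suffixes such as _1 when symbols were matched was decided after the table was seen. Lists with at least 5 measured genes were tested with limma's camera (3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 29 lists tested. Camera compares a list with the other genes. The fry test asks whether the genes of a list move on balance one way, and its mixed form whether they change in either direction.

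The rule for naming genes was also fixed beforehand. It takes relA and spoT first. It then takes the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher strain, replicates that do not overlap between strains, and a symbol or a product that is not hypothetical. It further takes up to 3 genes with the smallest adjusted p from each list, and rpoS, gacA, gacS, rsmA, rsmE, dksA and hfq whatever their p. The neighbours of relA and spoT, tuf_1 as the copy of tuf_2, pltM as an end of a plotted range, H78_05687 as a list member judged by its product, and the genes of runs and of the phosphate list are exceptions. Any other gene named outside this rule is said to have been chosen after its value was seen.

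The alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, a filter of 10 CPM in 3 samples, limma-voom, glmTreat against a log2 fold change of 1, a replicate block, each replicate left out in turn, and for the lists the estimated correlation and fry. Protein-coding genes alone, lists without members whose product shows a false match (such as "holin" inside "choline"), and lists without relA and spoT were added after seeing the data. The procedure was tested on simulated counts for 5863 genes with 50 genes changed at each fold size. In this simulation, edgeR recovered 44%, 80%, 96%, 100% of the genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, in that order. Of its calls, 9.6% were false. It called 177 genes there, against 3554 in the data, so these shares may not carry over to the real comparison.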

Results

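Gene expression was measured in 3 samples of the wild type and 3 samples of the (p)ppGpp0 mutant of *P. protegens* H78 in late exponential phase. Total counts per sample ran from 4674613 to 5606864, of which between 2090339 and 3220745 fell in coding genes. Coding genes took 45.2% ± 0.541 of the counts in the wild type and 57.5% ± 0.531 in the mutant (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples allow). Most other counts came from 2 stable RNAs, the transfer-messenger RNA ssrA (34.7% ± 0.799 and 28.9% ± 0.222) and the RNase P RNA (14.7% ± 1.25 and 7.38% ± 0.307). Correlations of log2 CPM across genes were at least 0.979 within a strain and at most 0.865 between strains. No pair of replicates agreed within sampling noise: the mean chi-square per gene was 5.07 or more, against an expectation of 1. Within a strain it was highest between mutant replicates 1 and 2 (23.9).

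Both targeted genes were lost in the mutant libraries. For relA (H78_04755, positions 5277669 to 5279912 on the minus strand), the counts were 1816, 1987 and 1964 in the wild-type samples and 0 in each mutant sample, so the transcript was at least 2109.6-fold lower. For spoT (H78_06273, positions 6840037 to 6842142 on the plus strand), the counts were 1752, 1736 and 1813 in the wild-type samples and 0, 1 and 0 in the mutant samples. This is a ratio of 5817 (95% counting interval 1044 to 229777). Beside relA, the RNA methyltransferase gene rumA rose (1.21 ± 0.14, log2 fold change and SE) and mazG did not pass (adjusted p = 0.546). Beside spoT, the endoribonuclease gene H78_06274 rose (1.82 ± 0.15) and the RNA polymerase omega subunit gene rpoZ fell (-0.38 ± 0.10).

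In the mutant, all measured pyoluteorin and pyrrolnitrin genes were lower, and most pyoverdine genes. The diacetylphloroglucinol list did not pass camera. The cyanide synthase genes, chosen after their values were seen, were higher, but their list split and did not pass. More genes were higher than lower on the lists for protein synthesis, ATP synthase, nucleotides, amino acids, chaperones and the flagellum. Camera called these last lists up at the preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.275). Of 5888 genes tested, 3554 changed, 1758 of them higher and 1796 lower in the mutant (edgeR quasi-likelihood test, adjusted p under 0.05). A change of at least 2-fold was seen for 1476 genes, 809 of them lower and the others higher. With protein-coding genes alone, an alternative added after seeing the data, 3551 changed. The authors' deposited table has 2887 genes with an adjusted p under 0.05. Of those, 2862 were called here in the same direction, and no gene called in both had opposite directions. Against a log2 fold change of 1 instead of 0, 407 genes were higher and 376 lower. Upper-quartile scaling shifted the median of all genes by -0.13 on the log2 scale and gave an uneven split, 1471 higher and 2170 lower, with 542 and 997 at 2-fold.

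Of the 31 lists, 29 had enough genes for a set test, and camera called 12 up and 6 down with the preset correlation. With an estimated correlation camera called 0 lists, and 1 list had an unadjusted p under 0.05. The fry test, which does not compare a list with the other genes, called 24 lists, and its mixed form 28. A pass by fry therefore sets a list little apart from the others.

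Counts of several lists depended on the setting. Upper-quartile scaling gave 2 lower ribosomal protein genes, 8 lower translation genes, 5 lower flagellar genes, 10 lower genes of branched-chain and aromatic amino acid synthesis and 1 lower ATP synthase or NADH dehydrogenase gene. DESeq2 gave 2 lower translation genes, 3 lower type IV pilus genes, 3 lower branched-chain and aromatic genes, 3 lower chaperone genes and 1 lower cell division gene. A filter of 10 CPM gave 8 lower translation genes, 5 lower flagellar genes, 10 lower cell division genes and 1 lower fatty acid gene. It also gave 9 higher terminal oxidase genes, 3 lower chaperone genes and 4 higher stress genes. That filter tested 4131 genes instead of 5888, so its counts may come from fewer list members. Without wild-type replicate 2 or mutant replicate 3, 3 translation genes and 1 nitrogen gene were lower. Without wild-type replicate 1, 3 translation genes were lower, and without wild-type replicate 2, 3 chaperone genes. In 8 settings, 1 pyoverdine gene was higher.

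**Figure D1:**
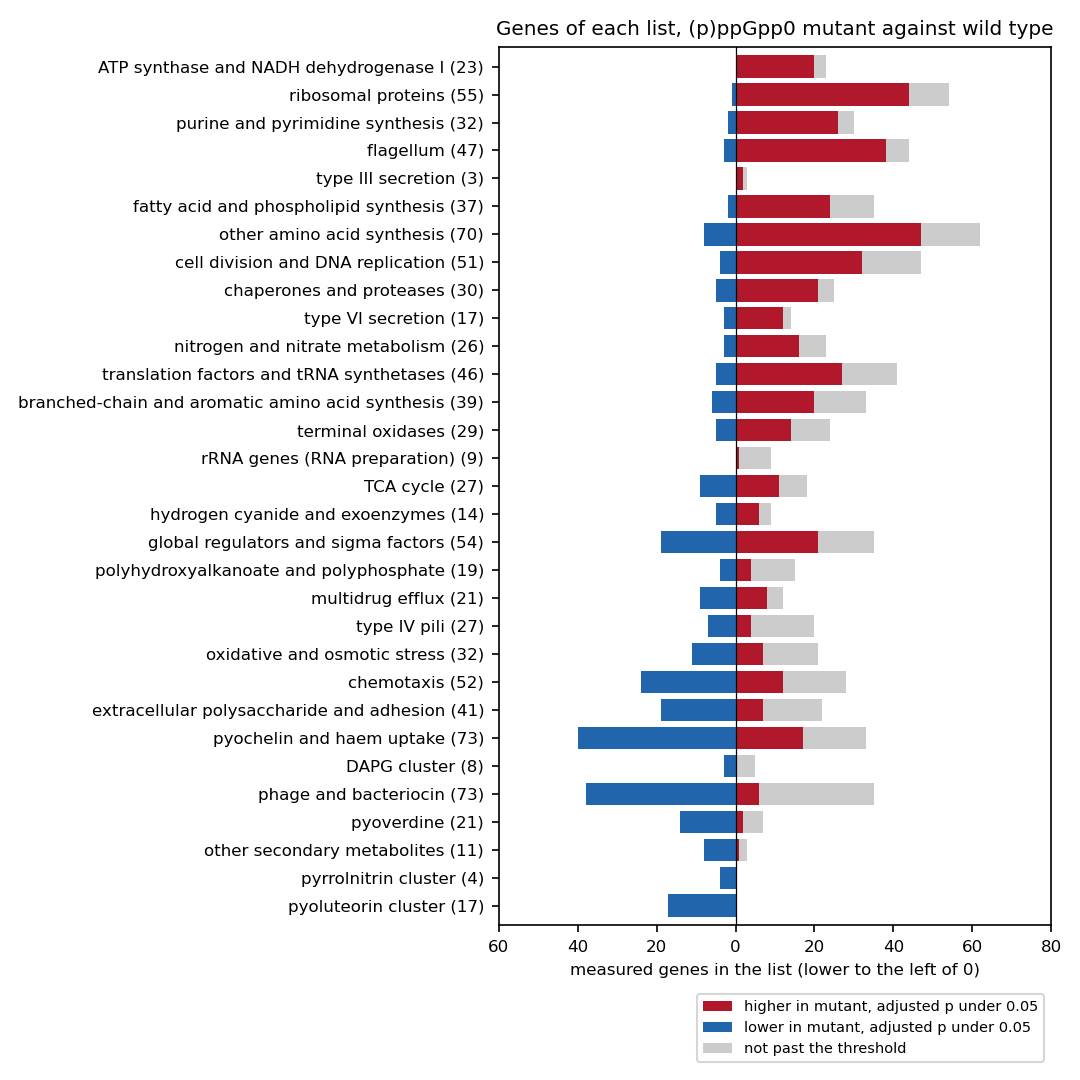
Bars give the number of measured genes of each list that were higher (red, right), lower (blue, left) or not past the threshold (grey) in the mutant, with the number measured in brackets and the number of genes on the x axis. The pyoluteorin cluster has 17 lower of 17, and ATP synthase and NADH dehydrogenase I has 20 higher of 23.

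Among genes with at least 10 CPM in the higher strain, the largest falls after relA and spoT were in pyoluteorin and R-body genes. Pyoluteorin is a chlorinated antibiotic, and its whole cluster fell: 17 of 17 measured genes were lower (0 higher and 17 lower adjusted over the list alone). Their median log2 fold change was -3.91 (camera adjusted p = 1.00e-08, and adjusted p = 0.275 with an estimated correlation). The halogenase gene pltA was at 1411 ± 883 CPM in the wild type and 18.9 ± 7.67 CPM in the mutant (SD, n = 3; log2 fold change -6.22, SE 0.52, adjusted p = 1.37e-05). The carrier protein gene pltL (log2 fold change -6.32 ± 0.58, SE) and the polyketide synthase genes pltC (-5.44 ± 0.40) and pltB (-5.34 ± 0.39) fell with it. Wild-type replicate 2 had the highest counts of these 4 genes, and without it the log2 fold change of pltA was -5.59. The transporter genes pltN and pltO (-3.81 ± 0.11 and -3.72 ± 0.12, SE) and the regulator gene pltZ (-2.82 ± 0.10) also fell, with adjusted p-values of 4.38e-08, 1.14e-07 and 1.14e-07. The adjacent genes rebB_1_2 and rebB_2, which encode R-body proteins, share reads, so their separate values are uncertain. Their summed level went from 872 ± 332 to 12.3 ± 3.81 CPM (SD, n = 3), and each passed the test (log2 fold changes -6.38 ± 0.34 and -6.00 ± 0.35, SE, adjusted p = 1.15e-06 and 1.92e-06).

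**Figure D2:**
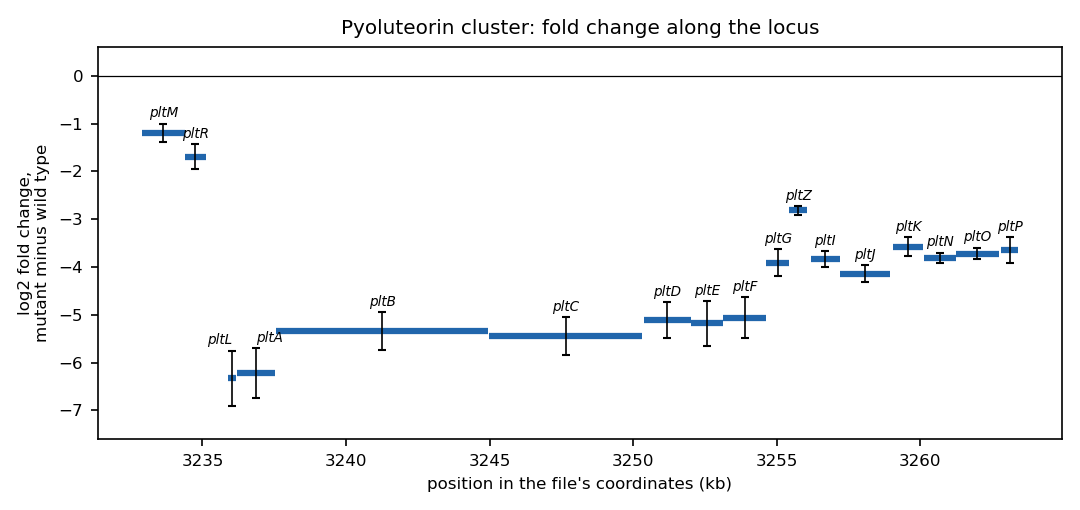
Blue bars show the extent of each of the 17 genes of the pyoluteorin cluster along the chromosome (x axis, kb) at its log2 fold change, mutant minus wild type (y axis), with the SE as error bars. All lie below 0, from -1.20 for pltM to -6.32 for pltL.

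Other antibiotic and toxin genes were lower in part. All 4 pyrrolnitrin genes fell (0 higher and 4 lower adjusted over the list alone, too few genes for the set test). The tryptophan halogenase gene prnA went from 67.4 ± 7.49 to 20.7 ± 1.77 CPM (log2 fold change -1.71, SE 0.12, adjusted p = 5.21e-06). For the antifungal diacetylphloroglucinol (DAPG), 3 of 8 genes fell and 5 did not pass (0 higher and 3 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.109, and adjusted p = 0.275 with an estimated correlation), although it passed fry (adjusted p = 4.60e-04). Upper-quartile scaling made this 5 lower, and without mutant replicate 2 a single gene was higher. The 3 that fell were phlG, which encodes the DAPG hydrolase (141 ± 3.89 CPM in the wild type and 6.8 ± 1.05 CPM in the mutant, log2 fold change -4.37, SE 0.12, adjusted p = 4.38e-08), the repressor gene phlF (-1.14 ± 0.17, SE) and phlH, whose call was lost with DESeq2 (adjusted p = 0.061), without wild-type replicate 2 (adjusted p = 0.0767) and without mutant replicate 3 (adjusted p = 0.0773). The synthesis genes phlA and phlD had log2 fold changes of -0.32 ± 0.14 and -0.06 ± 0.17 (SE, adjusted p = 0.0654 and 0.783) and were looked up after their values were seen. Among other secondary metabolites, 8 of 11 genes fell and 1 rose (2 higher and 8 lower adjusted over the list alone), the list passing with camera (camera adjusted p = 0.0379, and adjusted p = 0.275 with an estimated correlation). They included the orfamide synthetase genes ofaC (-1.32 ± 0.13, SE) and ofaB (-1.15 ± 0.11) and the insect toxin gene fitD (-1.45 ± 0.16). With a filter of 10 CPM, 4 of these genes were lower and the list did not pass (adjusted p = 0.322), nor did it with upper-quartile scaling (adjusted p = 0.064).

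The list of hydrogen cyanide and exoenzyme genes split, with 6 of 14 higher and 5 lower (6 higher and 5 lower adjusted over the list alone), and it did not pass (camera adjusted p = 0.849, and adjusted p = 0.896 with an estimated correlation). Its median log2 fold change was 0.17 and its mean -0.10. Without members matched by mistake, 4 of 12 were higher and 5 lower. The serine protease gene pspB fell from 61 ± 6.48 to 16.6 ± 1.8 CPM (log2 fold change -1.88, SE 0.13, adjusted p = 4.09e-06), as did a phospholipase C gene, H78_00924 (-1.82 ± 0.16, SE). The higher genes include lipA, which encodes lipoyl synthase rather than a lipase (0.80 ± 0.08, SE), and the cyanide synthase genes hcnA (1.01 ± 0.14), hcnB (0.95 ± 0.10) and hcnC (0.47 ± 0.11), the last 3 chosen after their values were seen.

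Genes on the lists for siderophores and haem uptake were lower on balance. Pyoverdine, the fluorescent siderophore, had 14 of 21 genes lower and 2 higher (2 higher and 15 lower adjusted over the list alone). The list's median was -0.73 (camera adjusted p = 0.00477, and adjusted p = 0.275 with an estimated correlation). The ferripyoverdine receptor gene fpvA went from 25.9 ± 4.89 to 7.96 ± 0.934 CPM (log2 fold change -1.70, SE 0.18, adjusted p = 4.47e-05), and the exporter gene pvdE changed by -1.29 ± 0.11 (SE), whereas fpvR, the anti-sigma factor gene, rose by 0.95 ± 0.12. For pyochelin and haem uptake, 40 of 73 genes were lower and 17 higher (17 higher and 43 lower adjusted over the list alone). As a list, they had a median of -0.64 (camera adjusted p = 0.0352, and adjusted p = 0.492 with an estimated correlation). This call was also lost with upper-quartile scaling (adjusted p = 0.0928), with a 10 CPM filter (adjusted p = 0.202) and without mutant replicate 2 (adjusted p = 0.0761). The pyochelin genes from pchA to pchD, a run chosen after the results were seen, fell further than the list median (median -3.84, range -4.70 to -3.19). Besides synthesis genes, some named for enantio-pyochelin, the run holds the transporter genes pchI and pchH. A receptor gene of unstated substrate, H78_00897, fell from 112 ± 39.4 to 8.82 ± 0.62 CPM (log2 fold change -3.67, SE 0.26, adjusted p = 5.65e-06). The largest rise in this list was exbD5, part of a TonB system that powers outer-membrane import, from 0.275 ± 0.238 to 96.9 ± 59.2 CPM (log2 fold change 8.38, SE 0.83, adjusted p = 3.41e-05). Its product name gives no substrate, so a role in iron uptake is not established for it.

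Most genes of protein synthesis rose. Of 55 ribosomal protein genes, 44 were higher and 1 was lower (44 higher and 1 lower adjusted over the list alone). Upper-quartile scaling made this 36 higher and 2 lower. The median over this list was 0.57 (camera adjusted p = 6.12e-07, and adjusted p = 0.45 with an estimated correlation). The ribosomal protein genes H78_05366 (1.16 ± 0.09, SE) and rpmB (0.82 ± 0.08) rose, and rpsO was the exception, at 1372 ± 106 CPM in the wild type and 642 ± 68.9 CPM in the mutant (log2 fold change -1.10, SE 0.10, adjusted p = 2.49e-05). A non-coding RNA entry overlaps the start of rpsO, so its count is uncertain. Translation factors and tRNA synthetases had 27 of 46 genes higher and 5 lower (27 higher and 6 lower adjusted over the list alone). Together they had a median of 0.44 (camera adjusted p = 8.67e-04, and adjusted p = 0.324 with an estimated correlation). The factor genes tsf (823 ± 57.5 to 1777 ± 59.7 CPM, log2 fold change 1.11, SE 0.08, adjusted p = 6.25e-06) and infA (2.22 ± 0.15, SE) rose. The gene tuf_2, for elongation factor Tu, shares reads with its copy tuf_1 (2.06 ± 0.09 and -0.05 ± 0.08, SE, adjusted p = 6.75e-07 and 0.606), and their sum was 5822 ± 262 CPM in the wild type and 9899 ± 355 CPM in the mutant. The rRNA left after depletion took 0.608% ± 0.501 of the counts in the wild type and 0.764% ± 0.356 in the mutant (SD, n = 3, exact two-sided permutation p = 0.6). Of 9 measured entries of the rRNA list, 1 was higher (1 higher and 0 lower adjusted over the list alone), the protein-coding gene rraA (0.35 ± 0.08, SE), and the list did not pass (camera adjusted p = 0.326, and adjusted p = 0.842 with an estimated correlation). The rRNA copies share reads, so single entries are uncertain. Replicate 2 of both strains had the highest rRNA share (1.18% and 1.16%). Without wild-type replicate 2, 9 entries were higher and the list passed (adjusted p = 0.0145). The list also passed camera with the replicate block (adjusted p = 0.0358).

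ATP synthase and NADH dehydrogenase I had 20 of 23 genes higher and 0 lower (20 higher and 0 lower adjusted over the list alone). Across the list the median was 0.72 (camera adjusted p = 1.15e-06, and adjusted p = 0.275 with an estimated correlation). The ATP synthase genes atpH, atpF and atpA rose, atpH from 281 ± 21 to 1002 ± 29.7 CPM (log2 fold change 1.83, SE 0.09, adjusted p = 6.75e-07). Terminal oxidases were mixed, with 14 of 29 higher and 5 lower (14 higher and 5 lower adjusted over the list alone), and did not pass camera (camera adjusted p = 0.196, and adjusted p = 0.492 with an estimated correlation) but passed fry (adjusted p = 0.0103). Upper-quartile scaling gave 9 higher and 9 lower. The cytochrome o genes cyoB_2 (1.16 ± 0.11, SE) and cyoA_2 (1.18 ± 0.13) rose, and ccoN_3, for a cbb3-type oxidase, fell (-0.88 ± 0.09). The TCA cycle list split, with 11 of 27 higher and 9 lower (11 higher and 9 lower adjusted over the list alone), a median of 0.11, a mean of -0.12, and no call by camera (camera adjusted p = 0.541, and adjusted p = 0.583 with an estimated correlation), although the list passed fry (adjusted p = 6.85e-04). The fumarase gene fumC_2 went from 1847 ± 61.1 to 73.1 ± 27.2 CPM (log2 fold change -4.66, SE 0.27, adjusted p = 1.78e-06), while the succinyl-CoA synthetase genes sucD (1.31 ± 0.08, SE) and sucC (1.25 ± 0.08) rose.

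Biosynthetic genes were mostly higher. For branched-chain and aromatic amino acids, 20 of 39 genes rose and 6 fell (21 higher and 6 lower adjusted over the list alone). The median of these genes was 0.36 (camera adjusted p = 0.0183, and adjusted p = 0.275 with an estimated correlation). The leucine pathway gene leuC rose from 103 ± 5.65 to 487 ± 129 CPM (log2 fold change 2.24, SE 0.17, adjusted p = 8.30e-06), and trpC of tryptophan synthesis by 1.68 ± 0.12 (SE). For the other amino acids, 47 of 70 genes rose and 8 fell (48 higher and 8 lower adjusted over the list alone). Their median log2 fold change was 0.67 (camera adjusted p = 1.34e-06, and adjusted p = 0.275 with an estimated correlation). Examples are dapB of lysine synthesis (59.7 ± 5.99 to 310.1 ± 34.2 CPM, log2 fold change 2.38, SE 0.12, adjusted p = 9.00e-07) and the glutamate synthase gene gltB (1.91 ± 0.07, SE). In purine and pyrimidine synthesis, 26 of 32 genes rose and 2 fell (26 higher and 3 lower adjusted over the list alone). The list's median was 0.59 (camera adjusted p = 7.01e-06, and adjusted p = 0.275 with an estimated correlation). The aspartate carbamoyltransferase gene pyrB rose from 41.6 ± 4.52 to 167 ± 11.8 CPM (log2 fold change 2.01, SE 0.11, adjusted p = 1.33e-06), along with pyrC (1.46 ± 0.09, SE) and carB (1.45 ± 0.10). In nitrogen and nitrate metabolism, 16 of 26 genes rose and 3 fell (17 higher and 3 lower adjusted over the list alone). As a list, they had a median of 0.78 (camera adjusted p = 8.67e-04, and adjusted p = 0.275 with an estimated correlation). The ammonium transporter gene amtB rose 8.41-fold (log2 fold change 3.07, SE 0.13, adjusted p = 4.90e-07) and the glutamine synthetase gene glnA 3.34-fold. In fatty acid and phospholipid synthesis, 24 of 37 genes rose and 2 fell (24 higher and 2 lower adjusted over the list alone). The median over this list was 0.54 (camera adjusted p = 7.32e-05, and adjusted p = 0.275 with an estimated correlation). The acyl carrier protein gene acpP rose by 1.68 ± 0.10 (SE) and fabD, for a malonyl transferase, by 1.26 ± 0.08.

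Chaperone and protease genes rose in 21 of 30 cases and fell in 5 (21 higher and 5 lower adjusted over the list alone). Together they had a median of 0.64 (camera adjusted p = 7.94e-05, and adjusted p = 0.275 with an estimated correlation). Some members matched by mistake, such as a copper chaperone-like protein gene and genes of pilus assembly, and without them 20 of 26 were higher and 3 lower. The co-chaperonin gene groS went from 33.7 ± 1.55 to 232 ± 36.2 CPM (log2 fold change 2.78, SE 0.13, adjusted p = 7.32e-07), the protease gene hslU rose 6.01-fold and the chaperone gene htpG 3.87-fold. In cell division and DNA replication, 32 of 51 genes rose and 4 fell (33 higher and 4 lower adjusted over the list alone). Across the list the median was 0.36 (camera adjusted p = 4.55e-04, and adjusted p = 0.275 with an estimated correlation). Upper-quartile scaling made this 10 lower, and 2 were lower without mutant replicate 3. The higher genes included the division genes ftsI (1.67 ± 0.10, SE) and ftsA (1.36 ± 0.08) and lexA, the repressor of the SOS response (1.81 ± 0.10). Stress genes split, with 7 of 32 oxidative and osmotic stress genes higher and 11 lower (7 higher and 10 lower adjusted over the list alone), and no call by camera (camera adjusted p = 0.457, and adjusted p = 0.87 with an estimated correlation). The list passed fry (adjusted p = 0.0437). The peroxiredoxin gene osmC fell (-1.55 ± 0.09, SE), as did a catalase gene, H78_04239 (-1.51 ± 0.11), while the bacterioferritin gene bfr_1 rose 12.7-fold.

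Of 54 global regulators and sigma factors, 21 were higher and 19 lower (21 higher and 19 lower adjusted over the list alone), and the list did not pass camera (camera adjusted p = 0.784, and adjusted p = 0.798 with an estimated correlation), although it passed fry in the other direction (adjusted p = 5.97e-04). Its median was -0.07 and its mean -0.33, while camera's direction was up, so the signs differ. The deleted genes relA and spoT are members, and without them, an alternative added after seeing the data that turned fry to up, 21 of 52 were higher and 17 lower. The mean was then 0.15, and camera still gave no call (adjusted p = 0.427). Transcripts of the stationary-phase sigma factor gene rpoS were at 1149 ± 58.8 CPM in the wild type and 1166 ± 72.7 CPM in the mutant (SD, n = 3), a log2 fold change of 0.02 that did not pass (adjusted p = 0.842) and whose sign turned with upper-quartile scaling, with a 10 CPM filter, and without wild-type replicate 1 or mutant replicate 1. The Gac two-component genes gacA (-0.11 ± 0.10, SE) and gacS (0.14 ± 0.11) and the RNA-binding regulator gene rsmA (-0.07 ± 0.14) did not pass (adjusted p = 0.38, 0.312 and 0.689). Its homologue rsmE fell (log2 fold change -0.80, SE 0.19, adjusted p = 0.00482). The gene dksA, whose protein acts with (p)ppGpp on RNA polymerase, rose from 186 ± 6.48 to 463 ± 23.7 CPM (log2 fold change 1.32, SE 0.08, adjusted p = 2.34e-06), and hfq, for an RNA chaperone, by 0.84 ± 0.10 (SE).

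Flagellar genes rose in 38 of 47 cases and fell in 3 (38 higher and 3 lower adjusted over the list alone). The median of these genes was 0.86 (camera adjusted p = 1.08e-07, and adjusted p = 0.275 with an estimated correlation). The basal-body rod genes flgB (59.5 ± 1.11 to 170.3 ± 12.9 CPM, log2 fold change 1.52, SE 0.09, adjusted p = 1.96e-06), flgF and flgG rose between 2.52-fold and 2.86-fold, whereas fliC, for flagellin, fell (-0.48 ± 0.08, SE, adjusted p = 8.14e-04), a gene chosen after its value was seen. Chemotaxis genes did not pass camera as a list (camera adjusted p = 0.195, and adjusted p = 0.275 with an estimated correlation), with 12 of 52 higher and 24 lower (12 higher and 25 lower adjusted over the list alone). They passed fry (adjusted p = 0.00235). The sensor kinase gene cheA rose (1.26 ± 0.08, SE) and the aerotaxis receptor gene aer_3 fell (-2.36 ± 0.09). In type VI secretion, a contact-dependent injection system, 12 of 17 genes rose and 3 fell (12 higher and 3 lower adjusted over the list alone). Their median log2 fold change was 0.76 (camera adjusted p = 0.00702, and adjusted p = 0.324 with an estimated correlation). The gene hcp, for the secreted tube protein, went from 191 ± 25.5 to 645 ± 131 CPM (log2 fold change 1.76, SE 0.16, adjusted p = 2.10e-05). Of 3 genes on the type III secretion list, 2 rose (3 higher and 0 lower adjusted over the list alone, too few for the set test). The list matched hrpA (0.96 ± 0.08, SE) and hrpB, which encode ATP-dependent helicases, and only H78_05687 (0.84 ± 0.13), for a chaperone, belongs to type III secretion by its product. Type IV pilus genes did not pass (camera adjusted p = 0.811, and adjusted p = 0.879 with an estimated correlation), with 4 of 27 higher and 7 lower (4 higher and 7 lower adjusted over the list alone), the PilZ gene H78_05560 falling (-1.18 ± 0.12, SE). In extracellular polysaccharide and adhesion, 19 of 41 genes fell and 7 rose (7 higher and 19 lower adjusted over the list alone). The list's median was -0.30 (camera adjusted p = 0.0252, and adjusted p = 0.45 with an estimated correlation). The gene of the large adhesin, lapA, went from 1924 ± 156 to 438 ± 28.4 CPM (log2 fold change -2.14, SE 0.09, adjusted p = 5.35e-07), and pslB of the Psl polysaccharide changed by -1.30 ± 0.11 (SE), while mucD, a periplasmic protease gene, rose (1.41 ± 0.08).

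Phage and bacteriocin genes fell in 38 of 73 cases and rose in 6 (6 higher and 38 lower adjusted over the list alone). As a list, they had a median of -0.68 (camera adjusted p = 7.94e-05, and adjusted p = 0.275 with an estimated correlation). The prohead peptidase gene H78_03735 went from 36.2 ± 7.71 to 3.22 ± 0.712 CPM (log2 fold change -3.48, SE 0.23, adjusted p = 3.54e-06). Some members matched "holin" inside "choline", and without the mismatched members 34 of 64 were lower and 4 higher. A 10 CPM filter left 20 lower. Multidrug efflux genes split, with 8 of 21 higher and 9 lower (8 higher and 9 lower adjusted over the list alone), a median of -0.05, a mean of 0.31, and no call (camera adjusted p = 0.849, and adjusted p = 0.976 with an estimated correlation). The pump genes acrA and acrB each rose 10.2-fold, acrB from 47.5 ± 1.86 to 483 ± 111 CPM (log2 fold change 3.35, SE 0.17, adjusted p = 1.03e-06), and the regulator gene mexT rose 5.77-fold. For storage polymers, 4 of 19 polyhydroxyalkanoate and polyphosphate genes were higher and 4 lower (4 higher and 4 lower adjusted over the list alone), with no call (camera adjusted p = 0.962, and adjusted p = 0.977 with an estimated correlation). The list matched antiporter subunit genes by mistake, and without them 4 of 14 were higher and 2 lower (camera adjusted p = 0.386). Upper-quartile scaling gave 8 lower and leaving out mutant replicate 2 gave 7 higher. The polyphosphate kinase gene ppk rose from 181 ± 9.12 to 1847 ± 78.2 CPM (log2 fold change 3.35, SE 0.08, adjusted p = 2.47e-08), and phaG_1, for an acyl transferase of polyhydroxyalkanoate synthesis, 8.33-fold.

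The largest rises by the naming rule were led by H78_01401, an ornithine acyltransferase gene (1.12 ± 0.467 to 789 ± 293 CPM, log2 fold change 9.41, SE 0.43, adjusted p = 6.75e-07), with the neighbouring acyltransferase gene H78_01400 (6.71 ± 0.34, SE), and by exbD5. The phosphate-binding protein gene pstS rose 159-fold, to 11567 ± 1466 CPM (log2 fold change 7.31, SE 0.17, adjusted p = 1.54e-08). The others were H78_01844, a helicase subunit gene (7.73 ± 0.16, SE), H78_05890, for an exported protein (7.31 ± 0.25), H78_06372, for a LysR-type regulator (7.10 ± 0.52), and H78_01928, for an alcohol dehydrogenase (128-fold). The counting is not stated to use strand, and H78_06372 overlaps a gene on the other strand, so its value is uncertain.

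**Figure D3:**
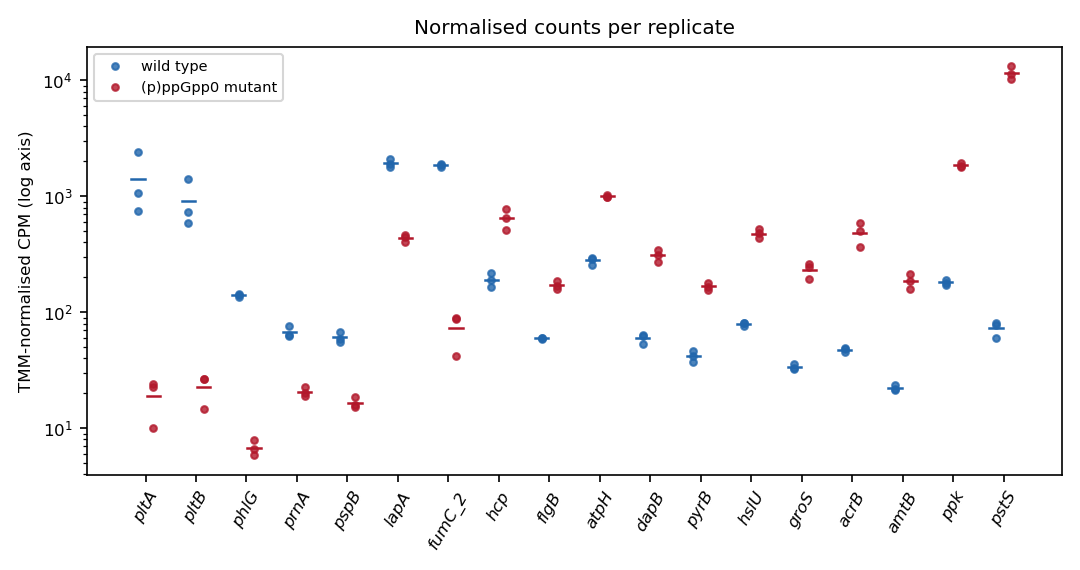
Points are TMM-normalised CPM (log axis) of 3 wild-type (blue) and 3 mutant (red) replicates for 18 genes named in the text, and lines are means. In these genes, named for a small adjusted p or a large change, the replicates of both strains do not overlap, which that choice favours. The gene pstS was at 72.6 CPM in the wild type and 11567 CPM in the mutant.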

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

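The alternatives other than glmTreat gave 2854 to 3641 changed genes, against 3554, with 2984 for DESeq2. The lowest count came with the 10 CPM filter, which tested 4131 genes instead of 5888. It called 69.1% of the genes it tested, against 60.4% in the main setting. Tested against a log2 fold change of 1, by construction a stricter test, glmTreat called 407 genes higher and 376 lower. That total, 7.8e+02, also stands against the 1476 genes changed at least 2-fold. Leaving out 1 replicate gave 3146 to 3495 changed genes, 1576 to 1773 higher and 1563 to 1722 lower, 1440.0 to 1535 at least 2-fold, 672 to 721 list members called and 17 to 19 lists called. With an estimated correlation camera called 0 of the 18 lists, and the cause was not tested. For global regulators and sigma factors, fry pointed down where camera pointed up (adjusted p = 5.97e-04). Without the deleted genes relA and spoT, an alternative added after seeing the data, fry pointed up (adjusted p = 1.66e-04), so the turn came from these members. Signs turned for genes that had not passed: rpoS was at -0.11 with upper-quartile scaling and -0.0926 with the 10 CPM filter and ran from -0.0244 to 0.0683 with 1 replicate left out. The others were rsmA, from -0.151 to 0.0267; rrlC, from -0.0172 to 1.27 and rrlD, from -0.0373 to 1.3, the cause not being tested. The highest values of both rRNA genes came without wild-type replicate 2, and both passed there. The tallies that follow leave out glmTreat. Of the values per named gene and setting, 1552 kept sign and side of the threshold and 3 lost the call (all phlH). A further 4 gained the call (rrlC and rrlD, each without wild-type replicate 2 and with the replicate block). Of the counts per list, 941 stayed within 1.5 times, 32 were smaller and 19 larger.

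The replicate block gave 3411 changed genes. The deviations of same-numbered samples from their group means correlated across genes at 0.0275, 2.35e-04 and 0.0372. Those of samples with different numbers ran from -0.0482 to 0.0148. Wild-type replicates 1 and 3 correlated best with the mutant replicate of the same number, and wild-type replicate 2 with mutant replicate 3. All these values are small, so the numbers were not read as pairs. The rRNA share was nevertheless highest in replicate 2 of both strains, and with the block the rRNA list passed (adjusted p = 0.0358). The tRNA genes had at most 1 count per sample, the reason not being tested. Genes changed 1.5-fold were recovered in 44% of simulated cases, a share that may not carry over because far fewer genes changed in the simulation.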

Other observations

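The runs of neighbouring genes, the phosphate list with its tests of single libraries and of phosphate shortage, and both tests on RNase P RNA were chosen after the results were seen, and the top genes of the pst locus had been seen before the test of its neighbours was written.

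There were 18 runs of at least 5 adjacent coding genes on 1 strand that all changed at least 4-fold in 1 direction with an adjusted p under 0.05, 10 higher and 8 lower in the mutant. The higher runs include the urt genes of urea transport (log2 fold change, median 3.46, range 2.88 to 4.55), the ped and pqqB_1 genes of alcohol oxidation with the cofactor PQQ (median 3.95, range 3.02 to 4.78), and the mtl genes of polyol use (median 2.77, range 2.18 to 3.14). In 3 runs genes of a TonB system rose, tonB4 beside a phytase gene (median 3.95, range 2.30 to 6.27), tonB5_1 beside a nucleotidase gene (median 5.97, range 3.85 to 8.38) and tonB6 (median 4.89, range 2.12 to 6.30). The highest of the tonB4 run was exbB4, with few wild-type counts, at 7.55 without wild-type replicate 1. In the tonB5_1 run the highest was exbD5, also with few wild-type counts. A run of 10 genes holds type II secretion genes and 2 alkaline phosphatase genes (median 2.85, range 2.06 to 5.80). The lower runs include the pyochelin synthesis and transporter genes from pchA to pchD (median -3.84, range -4.70 to -3.19). Another is the fetA receptor gene with its neighbours (median -4.31, range -4.47 to -2.55). A further one holds fatty acid desaturase genes with an AMP-binding protein gene (median -3.91, range -4.66 to -2.90). The reb run of 6 genes also fell, and its sigma factor gene, H78_00191, with 124 counts in the wild type and 0 in the mutant, was at least 45.4-fold lower.

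Genes of phosphate acquisition were higher in the mutant: 22 of 28 measured genes rose and 2 fell, with a median log2 fold change of 2.20, phoB at 5.65 ± 0.31 (SE), phoU at 5.12 ± 0.25 and oprO at 5.69 ± 0.42. The camera p was 2.14e-07, and p = 0.00426 with an estimated correlation, but the list was written after fold changes had been seen, so neither is independent evidence. The tables argue against a higher gene dosage around the pst locus, since the 162 other genes within 100 kb of pstS had a median log2 fold change of 0.23 (quartiles -0.26 and 0.72). They also argue against a single library as the source, since the list median ran from 1.87, without mutant replicate 1, to 2.52, without mutant replicate 2. The mutant samples still differed among themselves, with oprO at 824 ± 402 CPM and phoB at 1017 ± 399 CPM (SD, n = 3). A shortage of phosphate in the mutant cultures at harvest stays a candidate explanation beside an effect of the genotype itself: either may give 22 higher genes, and these cannot be told apart because strain and culture coincide.

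Fold changes fell with distance from dnaA, which starts at position 101 near the presumed replication origin. Across 5859 coding genes, which are not independent replicates, Spearman's rho was -0.213, and the median log2 fold change was 0.17 in the nearest 20% of genes and -0.35 in the farthest. The tables argue against the fixed lists as the whole reason, since without their members the difference between those 2 groups was 0.47. More rounds of replication per cell in the mutant remain a possible explanation, but it cannot be told apart from other differences between chromosome regions: the circular-shift p was 0.013 on the left arm (rho -0.247), 0.0579 on the right arm (rho -0.182) and 0.221 over the whole chromosome, with 1000 evenly spaced shifts. Among genes not called changed the difference was 0.0656, which decides nothing because these genes were chosen for small changes.

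RNase P RNA was lower in the mutant, at 145612 ± 13128 CPM against 74386 ± 4084 CPM (SD, n = 3; log2 fold change -0.97, SE 0.09, adjusted p = 2.68e-05). A second entry, rnpB, overlaps it on the same strand, and the sum of both changed by -0.97 on the log2 scale. The 15 tested non-coding RNAs of 200 to 450 nt other than both RNase P entries had a median log2 fold change of 0.115 (range -0.96 to 1.22). Many of them, such as the cspA and Cobalamin entries, carry names of mRNA leader elements. Their annotated length may not be that of the molecule, so this median cannot decide on a loss of short RNAs. Of the others, ssrA was at -0.24 and CrcZ at 0.18. Looked up after their values were seen, phrS was at 0.70 and P24 at -0.96. So was H78_04226, a less abundant entry that is also named CrcZ, which was at 1.08 (adjusted p = 0.00118). These values argue only against an equal loss of all short RNAs. The tables also argue against a smaller non-coding share alone. The mean log2 ratio of RNase P RNA to ssrA was lower in the mutant by a difference of -0.72, and no mutant library overlapped a wild-type library. As a hypothesis from the same data, the level of RNase P RNA may depend on (p)ppGpp, and no other library type was analysed here to test it.

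The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10 for each result, gave 3554 changed genes, 1758 higher and 1796 lower, against a highest other count of 0, where edgeR gave at most 56 genes with an unadjusted p under 0.05. For the lists called by camera with the preset correlation, the real split gave 18 and the highest other 16. Each other split still sets 2 samples of a strain against 1, so it carries part of the strain difference.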
